A study of Arabidopsis thaliana with 12 samples.

How the data were processed

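Total RNA was taken from leaves of Arabidopsis thaliana, per the labels' protocols. Plants were grown at 22 °C with 10 h of light and 14 h of dark until 4 weeks old, and fully expanded rosette leaves, 3 per plant, were infiltrated with 1 µM latrunculin B or with 0.01% DMSO. Leaves were frozen after 24 h, RNA was extracted with the RNeasy Mini kit, and libraries were made with the NEBNext Ultra II Directional kit. Groups were taken from the genotype and treatment labels, which give 4 groups of 3 libraries: WT with DMSO, WT with latrunculin B, sid2 with DMSO and sid2 with latrunculin B. The labels name no batch, plant number or pairing.

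The authors trimmed reads with Trimmomatic and quantified transcripts with Salmon 1.3.0 on TAIR10, per the submitters' processing notes. The 12 deposited tables hold, per the file headers, an estimated count of reads, a TPM value, a length and an effective length for each of 32875 transcripts. The deposited TPM values are those of Salmon, per the file headers, scaled within each library for effective length and depth. Nearly all lengths (99.99%) were multiples of 3, so the transcript models hold coding sequence without untranslated regions. Reads shared between near-identical genes were divided by the estimation model, so values of LHCB1 and RBCS copies, actins, tubulins and mitochondrial genes with nuclear copies (IDs starting AT2G07) are uncertain between the copies.

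The estimated counts were summed over transcripts to 27313 genes and rounded. Of these genes, 26645 had an entry in the TAIR10.1 reference annotation, which was used only for gene names and for the order of genes, and 668 kept their ID alone. Library totals ran from 14506962 to 22449387 estimated reads. Genes were filtered with filterByExpr, which left 18149, and libraries were scaled by TMM. CPM values use TMM-scaled library sizes, and errors are SD over 3 libraries. A fold against a group without reads is a lower bound, computed against 3 reads over the whole group, and such floors and bounds cover counting error only.

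The main test was the quasi-likelihood test of edgeR 4.0.16 under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. It used 1 model over the 12 libraries with a mean for each group, so the 4 groups shared 1 estimate of the spread. The common biological coefficient of variation was 0.211. The 5 comparisons were latrunculin B against DMSO in WT, the same in sid2, the difference of these responses (sid2 minus WT, the interaction), sid2 against WT under DMSO, and sid2 against WT under latrunculin B. A log2 fold change is positive where the first-named group is higher. Across-gene Pearson and Spearman correlations of the WT and sid2 responses were computed, and the overlap of passing genes was set beside the overlap of independent lists with Fisher's exact test. Genes are not independent replicates.

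Gene lists numbered 29 with 540 entries and 521 different genes. They covered SA synthesis and metabolism, SA response, N-hydroxypipecolic acid, camalexin, pattern-triggered immunity, WRKY factors, NLR receptors, jasmonate, ethylene, abscisic acid and water deficit, actin and actin-binding proteins, tubulins, secretion and exocyst, ER protein folding, cytosolic heat shock, oxidative stress and detoxification, photosynthesis and the Calvin cycle, the circadian clock, senescence, sugar starvation, autophagy, aliphatic glucosinolates, indole glucosinolates and tryptophan, cell wall expansion and cellulose, cell division, and markers of guard cells, phloem, xylem and epidermis. A further 3 entries were left out because the reference gives their ID another symbol. Each list with at least 5 tested members was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry. N-hydroxypipecolic acid had 4 tested members and no list test. Some genes are in several lists, such as CYP79B2 (camalexin and indole glucosinolates), UGT76B1 and SEN1.

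The comparisons, the main test, the lists, the alternatives other than scaling by library size alone, and the rule for named genes were fixed before the data were examined. The rule named ICS1, the 10 genes with the largest change in each direction among passing genes with an average log2 CPM of at least 1 and no overlap between the libraries compared (no such requirement for the interaction), up to 5 members with the smallest adjusted p of each list, and all members of both SA lists. Genes named beyond it, to identify the members behind a count of 5 or fewer, were chosen after their values were seen.

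The alternatives were RLE and upper-quartile scaling, no filter on low counts, robust hyperparameters, offsets with effective lengths, leaving out organelle genes, an absolute log2 fold change of at least 1, DESeq2 1.42.0, limma on log2(TPM + 1) for genes with a TPM of at least 1 in at least 3 libraries, a fit to the 6 libraries of a comparison alone, and leaving out each library in turn. Scaling by library size alone was added after the data were seen.

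The steps were tested on simulated counts drawn for the real genes from the means and library sizes of the real libraries, with 50 genes changed at each fold. For latrunculin B in WT (17929 genes run) 62% of 2-fold and 98% of 4-fold changes were recovered. For latrunculin B in sid2 (17946 genes run) these shares were 58% and 94%, and for the interaction (17929 genes run) 30% and 82%. For sid2 against WT they were 54% and 96% under DMSO (17926 genes run) and 62% and 98% under latrunculin B (17929 genes run). Between 6 and 10 unchanged genes passed in each comparison. A simulation with equal responses in both genotypes (17840 genes run) gave 6983 passing genes in WT, 6844 in sid2 and none in the interaction.

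Replicates were compared with sampling noise. The chi-square per gene between libraries of a group ran from 11.2 to 35.1 over genes with at least 20 reads in the pair, where repeated sequencing of the same library would give about 1. A list result between genotypes under latrunculin B is not reported here.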

Results

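RNA-seq libraries were made from rosette leaves of Arabidopsis thaliana 24 h after infiltration of 1 µM latrunculin B or 0.01% DMSO. Latrunculin B binds free actin and depolymerizes actin filaments. The plants were Col-0 wild type (WT) or sid2, a mutant of the isochorismate synthase gene ICS1, whose product starts the main route to salicylic acid (SA). The 4 groups held 3 libraries each. Totals of estimated reads were 16127876, 19657252 and 22449387 in WT with DMSO, 17208623, 15180467 and 17407205 in WT with latrunculin B, 17982949, 14506962 and 15842386 in sid2 with DMSO, and 21046209, 18502807 and 18317479 in sid2 with latrunculin B. Between 16577 and 17594 genes had at least 10 reads in a library, and 18149 genes were tested. The 10 most abundant genes took 8.66% to 10.9% of the reads in the WT libraries with latrunculin B and 14.1% to 17.9% in the other libraries. The first principal component of log2 CPM held 51.7% of the variance and set the WT libraries with latrunculin B (96.3 to 121) apart from all others (-11.3 or lower). On the third component (9.58%) sid2 DMSO replicate 3 lay at -11.4, and the other libraries of its group at 43.0 and 54.7. The labels do not say whether the libraries of a group came from separate plants, so p-values measure the spread between these samples.

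The targeted gene, ICS1 (AT1G74710), had 22.6 ± 1.19 CPM (SD, n = 3) in WT with DMSO and 136 ± 25.0 CPM in WT with latrunculin B. In the libraries labelled sid2 it was higher, at 370 ± 3.69 CPM with DMSO and 335 ± 44.4 CPM with latrunculin B. Single WT libraries lay between 21.6 and 161 CPM and single sid2-labelled libraries between 299 and 385 CPM. A mutant transcript can be made and counted, so the level of ICS1 transcripts does not test the lesion, and every direction between genotypes rests on the labels. The SA marker gene PR1 (AT2G14610) separated the labels in all 12 libraries, with 79.4 to 5267 CPM in WT and 0 to 7.59 CPM in the sid2-labelled libraries. The paralog ICS2 (AT1G18870) stayed at 13.2 CPM or less in every library.

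**Figure D1:**
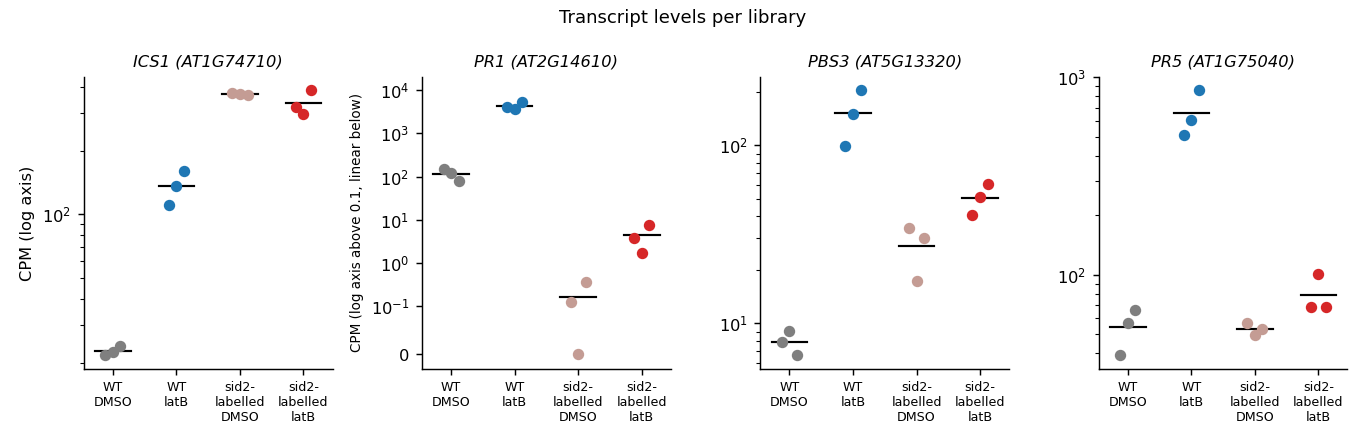
CPM of ICS1, PR1, PBS3 and PR5 on log axes (PR1 linear below 0.1) in the 12 libraries, by group; points are libraries and lines are group means. PR1 means were 118 CPM in WT with DMSO, 4367 CPM in WT with latrunculin B, and 0.160 and 4.38 CPM in the sid2-labelled groups, while ICS1 was highest in the sid2-labelled groups.

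Latrunculin B against DMSO in WT asks which transcripts respond to this actin drug. These data hold no measure of actin filaments in either genotype. In WT leaves 21 of 22 genes of SA response and 11 of 18 genes of SA synthesis rose. PR1, which encodes a secreted antimicrobial protein, rose 37.2-fold (log2 5.22 ± 0.42 SE, adjusted p = 1.02e-06 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The glucanase gene PR2 (AT3G57260) rose from 142 ± 41.2 to 800 ± 76.7 CPM, PR5 (AT1G75040) from 54.2 ± 13.9 to 660 ± 179 CPM, and the peptide gene PNP-A (AT2G18660) rose 19.6-fold. Of the 22 measured SA response genes 21 rose, the same 21 by count when adjusted over the list alone, and PCC1 did not pass (adjusted p = 0.128). PCC1 passed with scaling by library size alone (0.0242), by limma on TPM (0.0484), in a fit of the 6 WT libraries (0.0154), and without sid2 latrunculin B replicate 2 (0.021) or 3 (0.0439). The camera test of the list gave an adjusted p of 8.45e-15, and 0.022 with an estimated correlation. Among genes of SA synthesis ICS1 rose 5.99-fold, the amidotransferase gene PBS3 (AT5G13320) 19.3-fold, the regulator CBP60G (AT5G26920) 10.0-fold, its relative SARD1 (AT1G73805) 3.55-fold and the chloroplast exporter EDS5 (AT4G39030) 5.19-fold. In this list 11 of 18 genes rose and 3 fell, 11 and 3 also when adjusted over the list alone: ICS2 fell 3.53-fold, PAL2 (AT3G53260) fell 1.69-fold and PAL3 (AT5G04230) 1.65-fold. The PAL2 and PAL3 calls ended with scaling by library size alone (adjusted p = 0.0913 and 0.164) and by limma on TPM (0.271 and 0.274). The list test gave an adjusted p of 1.91e-06, and 0.0736 with an estimated correlation.

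Members of other defence lists rose with them in WT. NHL10 (AT2G35980), a membrane protein gene of pattern-triggered immunity, rose 82.9-fold to 114 ± 53.8 CPM, and the receptor kinase gene FRK1 (AT2G19190) rose 25.9-fold to 164 ± 39.0 CPM. The camalexin genes CYP71A13 (AT2G30770) and PAD3 (AT3G26830), whose enzymes make the indole phytoalexin of this species, rose 19.8-fold and 17.1-fold. Without WT DMSO replicate 1 the log2 rise of CYP71A13 was 4.95 and not 4.31. The methyltransferase gene PXMT1 (AT1G66700) went from 0.0711 ± 0.0199 to 14.8 ± 6.12 CPM, XTH10 (AT2G14620), a wall-loosening enzyme gene, from 0.275 ± 0.123 to 56.0 ± 36.0 CPM, and the hormone transporter ABCG40 (AT1G15520) from 0.557 ± 0.109 to 132 ± 123 CPM. Without WT latrunculin B replicate 3 the log2 rise of ABCG40 was 6.85 and not 7.90, and that of XTH10 6.91 and not 7.57. Of 8 camalexin genes 6 rose and CYP79B3 fell (list adjusted p = 0.00397, and 0.279 with an estimated correlation). Of 27 pattern-triggered immunity genes 14 rose and PHI-1 fell (0.000423, and 0.392 with an estimated correlation). Of 30 WRKY transcription factor genes 26 rose (5.03e-11, and 0.119 with an estimated correlation), among them WRKY46 (AT2G46400) 5.14-fold and WRKY50 (AT5G26170) 8.03-fold. Of 18 NLR receptor genes, which encode intracellular immune receptors, 10 rose (0.00356, and 0.400 with an estimated correlation), with ADR1 (AT1G33560) up 2.47-fold. Adjusted over the list alone the counts were the same, except that 1 WRKY gene also fell.

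All 17 measured genes of protein folding in the endoplasmic reticulum (ER) rose in WT, 17 also when adjusted over the list alone. The chaperone gene BIP2 (AT5G42020) rose 5.71-fold to 1083 ± 178 CPM, and the disulfide isomerase genes PDIL1-2 (AT1G77510) and PDIL1-1 (AT1G21750) rose 6.77-fold and 4.86-fold. The list had the smallest camera p of the comparison (adjusted p = 5.1e-34, and 0.00356 with an estimated correlation). Of 33 genes of oxidative stress and detoxification 25 rose and 2 fell, GSTU5 and FSD1, with the same counts adjusted over the list alone (list adjusted p = 3.25e-09, and 0.183 with an estimated correlation). The glutathione transferase genes GSTF2 (AT4G02520) and GSTU8 (AT3G09270) rose 5.70-fold and 34.6-fold. NDB2 (AT4G05020) and AOX1A (AT3G22370), which form an alternative mitochondrial electron route, rose 7.68-fold and 4.19-fold. Of 15 senescence genes 12 rose (0.000203, and 0.114 with an estimated correlation), among them SAG13 (AT2G29350, log2 4.56) and the transcription factor NAP (AT1G69490) 5.12-fold. Of 10 secretion genes 7 rose (0.000205, and 0.281 with an estimated correlation), among them the vesicle fusion genes SYP122 (AT3G52400) 4.50-fold and VAMP722 (AT2G33120) 2.70-fold. The count for senescence adjusted over the list alone was 12 higher and 1 lower, and that for secretion was 7.

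Most measured genes of photosynthesis, microtubules and the cell wall fell in WT. All 33 measured genes of photosynthesis and the Calvin cycle fell, 33 also when adjusted over the list alone (list adjusted p = 1.06e-16, and 0.183 with an estimated correlation). The chlorophyll synthesis gene PORB (AT4G27440) fell 4.82-fold, the light-harvesting gene LHCB1.1 (AT1G29920) from 16677 ± 2130 to 6178 ± 1163 CPM, and the Rubisco subunit gene RBCS3B (AT5G38410) from 12083 ± 912 to 4770 ± 1126 CPM, where near-identical copies share reads. Of 15 tubulin genes 13 fell, 13 also adjusted over the list alone (5.77e-07, and 0.183 with an estimated correlation), with TUB5 (AT1G20010) down 8.30-fold, TUB6 (AT5G12250) 3.14-fold and TUA5 (AT5G19780) 3.24-fold. Of 21 genes of cell wall expansion and cellulose 15 fell, 16 adjusted over the list alone (1.71e-07, and 0.0736 with an estimated correlation). The cellulose synthase genes CESA1 (AT4G32410) and CESA3 (AT5G05170) fell 3.39-fold and 2.79-fold, and the xyloglucan enzyme gene XTH4 (AT2G06850) fell 17.8-fold. Of 11 epidermis markers 9 fell, 10 adjusted over the list alone (0.00125, and 0.364 with an estimated correlation), among them the wax gene CER3 (AT5G57800) 4.07-fold. Of 32 genes of actin and actin-binding proteins 7 rose and 9 fell, 8 and 10 adjusted over the list alone, and the list did not pass by camera (0.466) but did by fry (0.0174). The myosin gene XI-2 (AT5G43900) rose 2.03-fold and its relative XI-1 (AT1G17580) fell 1.85-fold. ADF6 (AT2G31200), for a filament-severing protein, rose 2.87-fold, and the formin gene FH1 (AT3G25500) fell 5.96-fold.

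Across all genes 4012 rose and 4115 fell in WT. Scaling by library size alone moved the median of all genes by 0.34 on the log2 scale and gave 6818 higher and 2521 lower, and limma on TPM gave 6960 and 2380. The genes given with a fold or level for WT had the same direction under both, and the lists had the same direction with library size alone, while lists were not tested by limma on TPM.

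Latrunculin B against DMSO in the sid2-labelled leaves asks what remains of the response in plants labelled as a mutant of SA synthesis. These data hold no measure of SA. There 5 of 8 camalexin genes and 8 of 27 pattern-triggered immunity genes rose. CYP71A12 (AT2G30750), CYP71A13 and PAD3 rose 20.8-fold, 12.1-fold and 12.6-fold (adjusted p = 0.00305, 0.00691 and 0.00337, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). NHL10 rose 14.8-fold to 21.0 ± 8.75 CPM and FRK1 9.87-fold to 13.0 ± 4.78 CPM. Without sid2 DMSO replicate 3, the library apart on the third component, the log2 rises were 7.10 for CYP71A12, 4.93 for CYP71A13, 5.50 for PAD3, 5.01 for NHL10 and 4.95 for FRK1, each more than 1.5 times the fold with all libraries. Of 8 camalexin genes 5 rose, 6 adjusted over the list alone (list adjusted p = 9.2e-07, and 0.103 with an estimated correlation). Of 27 pattern-triggered immunity genes 8 rose, 14 adjusted over the list alone (2.94e-10, and 0.122 with an estimated correlation). Of 30 WRKY genes 11 rose, 22 adjusted over the list alone (5.95e-18, and 0.0924 with an estimated correlation), among them WRKY60 (AT2G25000) 2.58-fold, WRKY8 (AT5G46350) 6.57-fold and WRKY47 (AT4G01720) 2.72-fold.

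In the sid2-labelled leaves 5 of 22 SA response genes rose (PR1, PNP-A, WRKY18, ACD6 and NUDT6), 13 adjusted over the list alone (list adjusted p = 4.58e-08, and 0.0924 with an estimated correlation; edgeR camera). PNP-A rose 3.44-fold, and PR1 25.9-fold, from 0.160 ± 0.181 to 4.38 ± 2.98 CPM. Without sid2 DMSO replicate 3 the log2 rise of PR1 was 5.86, without sid2 latrunculin B replicate 3 it was 4.05, and with all libraries 4.69. PR2 and PR5 were at 137 ± 36.8 and 79.3 ± 18.3 CPM with latrunculin B against 157 ± 40.3 and 53.2 ± 3.58 CPM with DMSO, and neither passed (adjusted p = 0.69 and 0.157). In the SA synthesis list EDS5 rose 3.27-fold and ICS2 fell 3.47-fold, and 7 genes rose and 1 fell adjusted over the list alone (0.0212, and 0.261 with an estimated correlation; 0.0538 with effective-length offsets, 0.0686 without sid2 latrunculin B replicate 2 and 0.0716 without sid2 DMSO replicate 2). ICS1 did not pass (log2 -0.14 ± 0.14 SE, adjusted p = 0.631). Of 33 oxidative stress genes 12 rose, 17 adjusted over the list alone (2.03e-12, and 0.103 with an estimated correlation), among them GSTF2 3.78-fold and GSTU10 (AT1G74590) 6.73-fold. Of 17 ER folding genes 5 rose, 12 higher and 1 lower adjusted over the list alone (5.4e-06, and 0.103 with an estimated correlation), with BIP2 up 1.74-fold. Of 17 ethylene genes, for a gaseous defence hormone, 7 rose, 7 also adjusted over the list alone (2.87e-06, and 0.103 with an estimated correlation). The transporter gene PHT3;2 (AT3G48850) and the receptor channel gene GLR2.5 (AT5G11210) had no reads in sid2 with DMSO and were at least 27.4-fold and 22.9-fold higher with latrunculin B (GLR2.5 did not pass by limma on TPM, 0.13). The jasmonate and ethylene regulator ORA59 (AT1G06160) was at least 25.4-fold higher.

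In the sid2-labelled leaves 5 of 20 genes of abscisic acid and water deficit and 6 of 10 phloem markers fell. The cold- and drought-responsive genes KIN2 (AT5G15970), COR47 (AT1G20440) and COR15B (AT2G42530) fell 3.02-fold, 2.24-fold and 4.25-fold. Of 20 genes of abscisic acid and water deficit 5 fell, 7 adjusted over the list alone with 1 higher (list adjusted p = 2.87e-06, and 0.157 with an estimated correlation; edgeR camera). The phloem loading gene SUC2 (AT1G22710) fell 2.07-fold from 255 ± 11.8 to 124 ± 5.86 CPM, and 6 of 10 phloem markers fell, 6 also adjusted over the list alone (7.55e-06, and 0.103 with an estimated correlation). None of the photosynthesis, tubulin, cell wall, actin or epidermis genes passed by edgeR, also adjusted over the list alone. The photosynthesis list passed as lower by camera (2.18e-05, 0.515 with an estimated correlation, and 0.164 by fry) with a median log2 fold change of -0.27.

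In all, 640 genes rose and 219 fell in the sid2-labelled leaves. Scaling by library size alone moved the median of all genes by 0.15 on the log2 scale and gave 1346 higher and 127 lower, and limma on TPM gave 888 and 93. The count of 859 rested on single libraries: it was 369, 496 and 378 without sid2 latrunculin B replicates 1, 2 and 3, and 447, 419 and 1472 without sid2 DMSO replicates 1, 2 and 3.

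**Figure D2:**
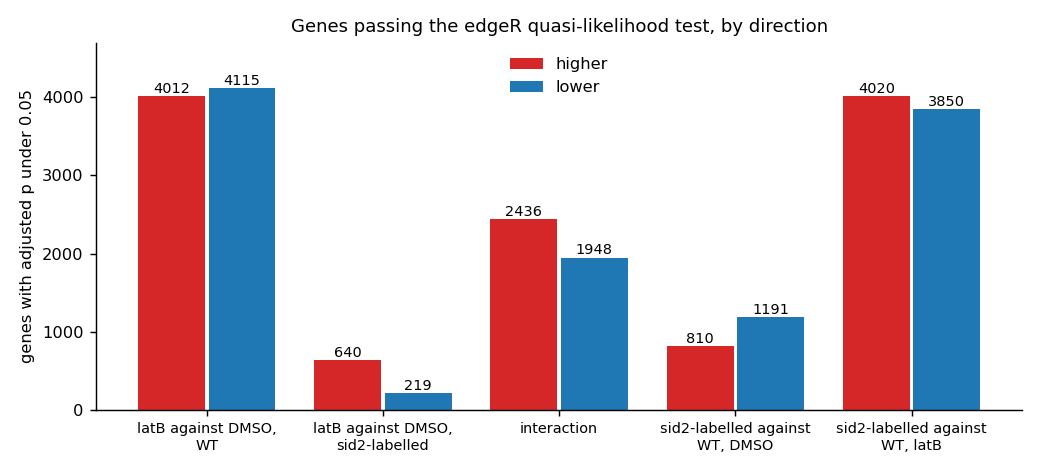
Number of genes passing the edgeR quasi-likelihood test (adjusted p under 0.05) in each comparison, as bars for genes higher and lower in the first-named group. WT had 4012 genes higher and 4115 lower under latrunculin B, and the sid2-labelled leaves 640 and 219.

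The interaction tests whether the response to latrunculin B differed between the genotypes. Of the 4012 genes that rose in WT 1718 had a lower log2 response in the sid2-labelled leaves by this test. Another 4 had a higher one, and the remainder did not pass. The WT libraries that chose these genes also enter the interaction, which favours the lower direction. Over all genes 2436 had a higher and 1948 a lower log2 response. BIP3 (AT1G09080) rose in WT from 16.8 ± 2.03 to 173 ± 40.1 CPM and was at 25.0 ± 6.06 and 15.7 ± 1.85 CPM in the sid2-labelled leaves (difference of log2 responses -4.03 ± 0.29 SE, adjusted p = 2.57e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). PDIL1-2 and the calreticulin gene CRT1B (AT1G09210) differed by -2.18 and -2.06. Of 17 ER folding genes 16 had a lower log2 response in the sid2-labelled leaves, 16 also adjusted over the list alone, and the list was the only one of this comparison to hold with an estimated correlation (camera adjusted p = 1.21e-28, and 0.00494). ICS1 differed by -2.73, PBS3 by -3.37, CBP60G by -2.45, PR2 by -2.70, PR5 by -3.03, AIG1 (AT1G33960) by -2.79 and PNP-A by -2.51. Of 22 SA response genes 8 differed in this direction, 8 also adjusted over the list alone (4.1e-06, and 0.137 with an estimated correlation), and of 18 SA synthesis genes 8 did, with 1 in the other direction adjusted over the list alone (3.68e-05, and 0.137 with an estimated correlation). PR1 did not pass by edgeR (adjusted p = 0.808, and 0.00383 by limma on TPM). Its level was at most 7.59 CPM in the sid2-labelled libraries and at least 79.4 CPM in WT. A similar log2 response is thus no similar rise in transcripts. Of the SA genes above ICS1, PBS3, CBP60G and AIG1 were already higher in the sid2-labelled leaves under DMSO. ICS1 had 365 to 372 CPM there against 21.6 to 23.9 CPM in WT. It was also higher under latrunculin B, at 299 to 385 against 111 to 161 CPM.

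Here the choice of genes by the WT libraries favours the opposite direction. Of the 4115 genes that fell in WT 2233 had a higher log2 response in the sid2-labelled leaves by the interaction. Only 1 had a lower one, and the remainder did not pass. XTH4 differed by 4.12, CESA1 by 1.81 and CESA3 by 1.47, and 14 of 21 cell wall genes differed in this direction, 17 adjusted over the list alone (camera adjusted p = 1.25e-09, and 0.0668 with an estimated correlation). TUB5 differed by 2.82 and TUB6 by 1.60, and 10 of 15 tubulin genes did, 14 adjusted over the list alone (5.28e-09, and 0.151 with an estimated correlation). PORB differed by 1.86, RBCS3B by 1.41 and LHCB2.2 (AT2G05070) by 1.02, and 29 of 33 photosynthesis genes did, 33 adjusted over the list alone (5.31e-11, and 0.400 with an estimated correlation). CER3 differed by 2.14, and 9 of 11 epidermis markers did, 10 adjusted over the list alone (5.93e-05, and 0.400 with an estimated correlation). SUC2 (-1.21), the sugar exporter gene SWEET12 (AT5G23660, -3.93) and the phosphatase gene HAI1 (AT5G59220, -3.31) were among genes with opposite trends. With latrunculin B against DMSO they were higher or level in WT and lower in the sid2-labelled leaves. Between genotypes under DMSO the phloem and abscisic acid lists had medians of 0.45 and 0.88, higher in the sid2-labelled leaves. Under latrunculin B these medians were -0.16 and -0.19, and neither list passed by camera (adjusted p = 0.652 and 0.773). Of 10 phloem markers 6 differed, 6 lower and 1 higher adjusted over the list alone (0.00532, and 0.400 with an estimated correlation), and of 20 abscisic acid genes 7 were lower and CYP707A3 higher, 8 and 2 adjusted over the list alone (0.000818, and 0.439 with an estimated correlation). NDB2 (-2.69) and AOX1A (-1.69) had lower log2 responses in the sid2-labelled leaves, as did 7 of 33 oxidative stress genes, while CSD2 had a higher one, with the same counts adjusted over the list alone. That list passed at 0.00602 (0.568 with an estimated correlation; 0.128 by fry and 0.108 without sid2 DMSO replicate 3).

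The camalexin list did not pass the interaction by camera (adjusted p = 0.484), and 1 of its 8 genes did, CYP79B2 (AT4G39950), which also feeds indole glucosinolates (-2.52), 1 also adjusted over the list alone. The pattern-triggered immunity list (0.484) and the WRKY list (0.0861) did not pass by camera either. By camera the WRKY list passed without sid2 DMSO replicate 2 (0.0108). It also passed without WT latrunculin B replicate 1 (0.0444) and without WT DMSO replicate 3 (0.021). By the directional test of fry, camalexin (0.579), pattern-triggered immunity (0.729) and WRKY (0.274) did not pass. By its test for changes in either direction they did (0.00383, 0.0274 and 0.00044), as did most lists. Of 27 pattern-triggered immunity genes 2 had a higher and 2 a lower log2 response in the sid2-labelled leaves. No gene of that list passed adjusted over the list alone. Of 30 WRKY genes 5 had a lower log2 response in the sid2-labelled leaves (WRKY41, WRKY46, WRKY50, WRKY51 and WRKY70) and WRKY22 a higher one, 5 and 1 also adjusted over the list alone, and WRKY51 (AT5G64810) differed by -3.74. In all, 2436 genes had a higher and 1948 a lower log2 response in the sid2-labelled leaves. With scaling by library size alone, which moved the median by -0.19, these counts were 1820 and 2975, and by limma on TPM 1568 and 3497.

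Genes that rose in WT had a median log2 fold change of 0.98 there and 0.21 in the sid2-labelled leaves, and genes that fell had -1.03 and -0.13. Genes that rose in the sid2-labelled leaves had 1.27 there and 1.33 in WT, and genes that fell there had -0.82 and -0.28. By the interaction 110 of the 640 genes that rose in the sid2-labelled leaves had a higher log2 response there than in WT. Another 112 had a lower one. Of the 219 that fell 90 had a lower log2 response there and 11 a higher one. Each set was chosen by libraries that enter its own response, which favours a larger response in the genotype that chose it. Of the 640 genes that rose in the sid2-labelled leaves 457 also rose in WT, where independent lists would share 141 (Fisher's exact test, odds ratio 9.80), and of the 219 that fell 85 also fell in WT, where 49.7 would be shared (odds ratio 2.19). Across 18149 genes, which are not independent replicates, the log2 fold changes of the genotypes correlated with Pearson r = 0.406 and Spearman rho = 0.293, and no library was shared between them. AT4G01390 moved in opposite ways, from 0.0308 ± 0.0534 to 9.96 ± 3.74 CPM in WT and from 7.38 ± 6.51 to 0.0364 ± 0.0630 CPM in the sid2-labelled leaves, where limma on TPM did not pass it (adjusted p = 0.0578). Its single sid2 libraries with DMSO were uneven, at 13.1, 8.79 and 0.285 CPM in replicates 1, 2 and 3.

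**Figure D3:**
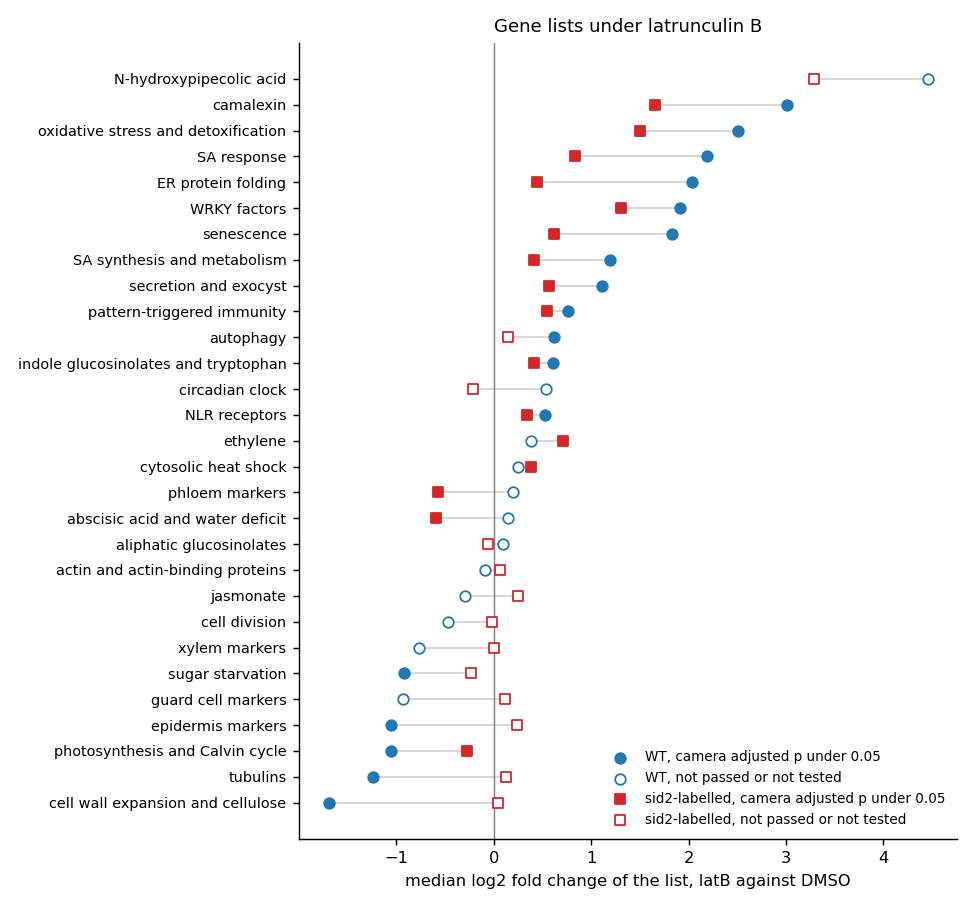
Median log2 fold change under latrunculin B of the 29 gene lists in WT (circles) and in the sid2-labelled leaves (squares), filled where the camera test at the preset correlation passed. Cell wall, tubulin and epidermis lists lie at -1.69, -1.24 and -1.05 in WT and near 0 in the sid2-labelled leaves, while the camalexin and WRKY lists lie above 1 in both.

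**Figure D4:**
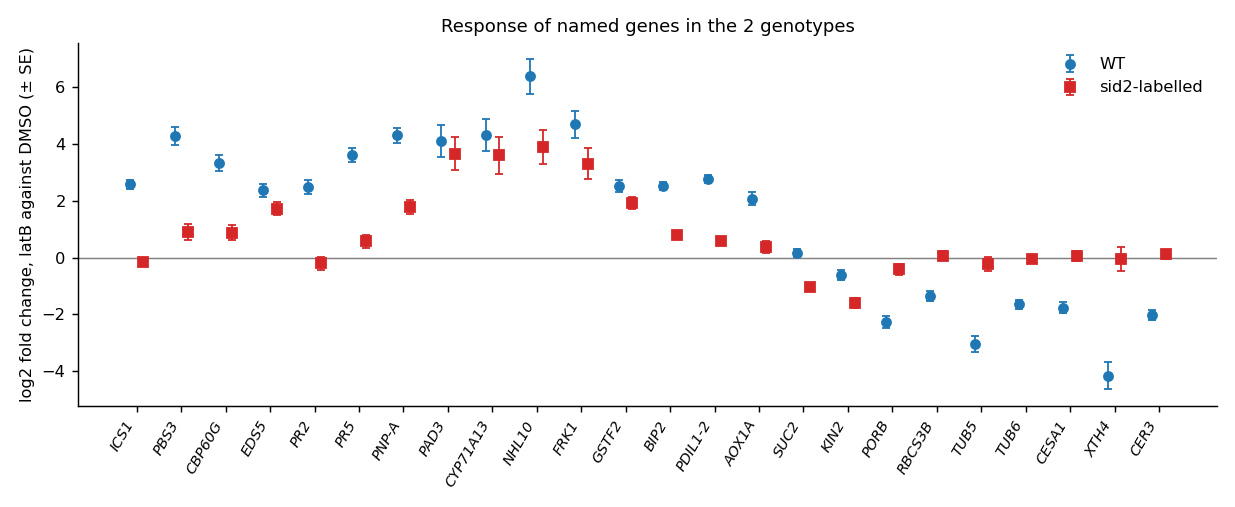
Log2 fold change under latrunculin B (points, with SE from edgeR as bars) of 24 named genes in WT (circles) and in the sid2-labelled leaves (squares). PAD3, CYP71A13 and GSTF2 rose in both, and TUB5, CESA1 and XTH4 passed as lower in WT alone.

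The genotypes under DMSO were compared to describe the effect of the mutation in mock-infiltrated leaves. Of 22 SA response genes 14 were lower in the sid2-labelled leaves. UGT76B1 (AT3G11340), a glucosyltransferase gene of SA and N-hydroxypipecolic acid, had no reads there and was at least 85.9-fold lower, and the regulators NIMIN1 (AT1G02450) and WRKY38 (AT5G22570) were at least 57.2-fold and 36.4-fold lower. The dioxygenase gene ARD3 (AT2G26400) and MRD1 (AT1G53480), a gene of unknown function, were at least 81.2-fold and 154-fold lower. PR1 fell to 0.160 ± 0.181 CPM against 118 ± 37.1 CPM in WT (log2 -9.44, and -10.60 without sid2 DMSO replicate 3), and PCC1 (AT3G22231) was 61.9-fold lower (adjusted p = 3.71e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), while PR2 and PR5 did not pass (0.746 and 0.956). Of 22 SA response genes 14 were lower and 2 higher (WRKY46 and AIG1), or 14 and 3 adjusted over the list alone (camera adjusted p = 2.4e-15, and 0.0237 with an estimated correlation). In the SA synthesis list 4 genes were lower and 3 higher, 4 and 7 adjusted over the list alone, and it did not pass (0.0615). That list passed as higher with effective-length offsets (0.0467), and without sid2 DMSO replicate 1 (0.0438) or 2 (0.0129), WT latrunculin B replicate 1 (0.0318) or 3 (0.0309), or WT DMSO replicate 3 (0.0419). The SA hydroxylase genes DMR6 (AT5G24530) and DLO1 (AT4G10500) were 3.35-fold and 6.88-fold lower, and ICS1 and PBS3 16.3-fold and 3.48-fold higher; SARD1 and SOT12 were also lower and CBP60G higher. The calls of SARD1, CBP60G, SOT12, WRKY46 and AIG1 each ended when single libraries were left out. The largest adjusted p was 0.0993 for SARD1 (without WT DMSO replicate 3), 0.0776 for CBP60G and 0.0771 for WRKY46 (both without WT DMSO replicate 1), 0.124 for SOT12 (without WT DMSO replicate 3) and 0.166 for AIG1 (without sid2 DMSO replicate 1).

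Of 31 jasmonate genes 6 were lower with them, and of 27 pattern-triggered immunity genes 7. WRKY60 was 3.07-fold lower, the chitin receptor gene CERK1 (AT3G21630) 2.06-fold and the kinase gene MPK11 (AT1G01560) 4.04-fold. The jasmonate-induced TAT3 (AT2G24850) was 14.6-fold lower, the jasmonate synthesis gene LOX3 (AT1G17420) 4.92-fold and JAR1 (AT2G46370), whose enzyme activates jasmonate, 2.48-fold. Without WT DMSO replicate 3 the log2 difference of LOX3 was -1.66 and not -2.30. Of 30 WRKY genes 10 were lower and WRKY46 higher, 11 and 1 adjusted over the list alone (camera adjusted p = 2.57e-05, 0.554 with an estimated correlation, and 0.0517 by fry). Of 27 pattern-triggered immunity genes 7 were lower, 10 adjusted over the list alone (0.000198, 0.612 with an estimated correlation, and 0.0639 by fry). Of 31 jasmonate genes 6 were lower, 6 also adjusted over the list alone (0.000481, and 0.612 with an estimated correlation; 0.116 by fry and 0.112 without WT DMSO replicate 3).

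Some genes of water deficit, glucosinolates and phloem passed as higher in the sid2-labelled leaves with DMSO. NCED3 (AT3G14440), which encodes the first committed enzyme of abscisic acid synthesis, was 3.10-fold higher, the proline synthesis gene P5CS1 (AT2G39800) 3.50-fold and the transcription factor HB12 (AT3G61890) 2.86-fold. Of 20 abscisic acid genes 8 were higher, 12 adjusted over the list alone (camera adjusted p = 7.2e-07, and 0.473 with an estimated correlation). Of 16 genes of aliphatic glucosinolates, sulfur-rich defence compounds, 6 were higher, 15 adjusted over the list alone (9.78e-08, and 0.473 with an estimated correlation), among them SOT17 (AT1G18590, log2 1.14), FMO-GS-OX3 (AT1G62560) 2.03-fold and BAT5 (AT4G12030) 1.96-fold. Of 10 phloem markers 4 were higher (SUC2, PP2-A1, AHA3 and APL), 4 also adjusted over the list alone (0.000327, and 0.473 with an estimated correlation), with SUC2 and PP2-A1 (AT4G19840) up 1.79-fold and 1.68-fold. In all, 810 genes were higher and 1191 lower, 552 and 1536 with scaling by library size alone, and 519 and 1142 by limma on TPM. The count of 2001 was 1094 without sid2 DMSO replicate 1, and 1035 and 1291 without WT DMSO replicates 1 and 2.

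Under latrunculin B the genotypes were compared for the state of the treated leaves. ARD3 had 455 ± 207 CPM in WT and no reads in the sid2-labelled leaves, a difference of at least 8879-fold, and WRKY38 and AT3G47050 were at least 235-fold and 158-fold lower. PR1 was 997-fold lower (log2 -9.96 ± 0.53 SE, adjusted p = 5.89e-08, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and log2 -10.61 without sid2 latrunculin B replicate 3. PR2 and PR5 were 5.85-fold and 8.32-fold lower. XTH10 had 0.0690 ± 0.0601 CPM in the sid2-labelled leaves. Of 22 SA response genes 21 were lower and WRKY53 did not pass, 21 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.19e-22, and 0.0072 with an estimated correlation). All 17 ER folding genes were lower, 17 also adjusted over the list alone (1.26e-27, and 0.0072 with an estimated correlation), with PDIL1-2 down 4.83-fold. All 33 photosynthesis genes were higher, 33 also adjusted over the list alone (2.18e-16, and 0.308 with an estimated correlation). Of 15 tubulin genes 13 were higher, 13 also adjusted over the list alone (2.21e-06, and 0.308 with an estimated correlation), among them TUB5 8.68-fold and TUB6 3.12-fold. Of 21 cell wall genes 14 were higher and XTH24 lower, with the same counts adjusted over the list alone (5.91e-06, and 0.174 with an estimated correlation), among them CESA1 2.90-fold and the expansin gene EXPA11 (AT1G20190) 8.42-fold. Of 30 WRKY genes 19 were lower and 1 higher, 19 and 2 adjusted over the list alone (3.71e-07, and 0.308 with an estimated correlation). The wax regulator ESE3 (AT5G25190) was 22.4-fold higher. ICS1, PAL2 and PAL3 were 2.47-fold, 2.59-fold and 2.03-fold higher, and 9 of 18 SA synthesis genes were lower, 4 higher and 9 lower adjusted over the list alone (0.0182, and 0.455 with an estimated correlation). In all, 4020 genes were higher and 3850 lower. Scaling by library size alone, which moved the median of all genes by -0.28, gave 2731 and 6071, and limma on TPM 2643 and 6096.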

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

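The results below stood out because the response to latrunculin B differed between the genotypes. Predictions for fewer reads, for scaling of the mitochondrial genes, for the splits and for the genes next to ICS1 were written before their results were seen, and the other tests were chosen after the patterns were seen.

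The interaction passed for 4384 genes. Among SA genes the difference of log2 responses (sid2-labelled minus WT) was -2.73 for ICS1, -3.37 for PBS3, -2.45 for CBP60G, -2.70 for PR2, -3.03 for PR5, -2.79 for AIG1, -2.51 for PNP-A and -3.74 for WRKY51. Of these SA genes ICS1, PBS3, CBP60G and AIG1 were already higher in the sid2-labelled leaves under DMSO. Among ER folding genes the difference was -2.18 for PDIL1-2, -4.03 for BIP3 and -2.06 for CRT1B. Genes that fell in WT had positive differences: PORB 1.86, RBCS3B 1.41, LHCB2.2 1.02, TUB5 2.82, TUB6 1.60, CESA1 1.81, CESA3 1.47, XTH4 4.12 and CER3 2.14. The indole gene CYP79B2 differed by -2.52, the water-deficit genes HB12 and HAI1 by -2.08 and -3.31, the sugar transporters SUC2 and SWEET12 by -1.21 and -3.93, NDB2 and AOX1A by -2.69 and -1.69, and the guard cell channel gene KAT1 by -2.97. The water-deficit and phloem lists were already higher in the sid2-labelled leaves under DMSO, with medians of 0.88 and 0.45. Among further genes outside the lists the difference was 5.87 for AT4G34950, 6.30 for AT2G16660, 4.83 for AT4G23820, -4.73 for CHX17 and -4.97 for AT2G26695. Without sid2 DMSO replicate 3 AT4G34950 and AT2G16660 stood at 6.74 and 7.27, and without WT latrunculin B replicate 3 CHX17 stood at -4.10. List medians of this difference were -0.72 for SA synthesis, -0.68 for SA response, -1.16 for abscisic acid and water deficit, 1.29 for tubulins, -1.63 for ER folding, -1.11 for oxidative stress, 0.78 for photosynthesis, -0.59 for the circadian clock, -0.77 for senescence, -0.59 for autophagy, 1.88 for cell wall, -0.79 for phloem and 1.25 for epidermis. Of these lists the clock passed at an adjusted p of 0.0123 (camera, Benjamini-Hochberg; 0.439 with an estimated correlation), autophagy at 0.00867 (0.439) and senescence at 0.0406 (0.422). The senescence call ended with library size alone (0.0748), and without sid2 latrunculin B replicate 3 (0.05), sid2 DMSO replicate 3 (0.098), WT latrunculin B replicate 2 (0.0563) or 3 (0.0619), or WT DMSO replicate 1 (0.0815).

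The wider response in WT than in the sid2-labelled leaves remained under other scalings, where at least 4336 genes passed the interaction. Library size alone turned the balance of these calls, from 2436 higher and 1948 lower to 1820 and 2975. All scalings are relative, so a change of total RNA per leaf was not tested. With all libraries thinned to the lowest total, WT still had 9.72 times as many called genes. Genes that rose in WT had a median log2 fold change of only 0.21 in the sid2-labelled leaves. A larger spread hides calls but would not by itself lower a median over many genes. In the simulation with equal responses, and equal spread in all groups, such genes kept 1.06, against 1.14 in WT. The median of 0.21 was not recomputed without sid2 DMSO replicate 3. Without that library 8525 genes passed in WT, 1472 in the sid2-labelled leaves and 4542 in the interaction. A biological reading, as a hypothesis, is that SA is needed for much of the response at 24 h, which would be consistent with these values. Time course, cell death, tissue state and the action of the drug on actin filaments in each genotype were not measured.

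ICS1 transcripts were higher in the sid2-labelled libraries. Single swapped libraries do not explain it, since the highest PR1 level of a sid2-labelled library was 7.59 CPM and the lowest of a WT library 79.4 CPM. The other genes of the SA synthesis and metabolism list had a median log2 difference of 0.0636 under DMSO (SD 1.09), against 4.03 for ICS1. The list as a whole thus did not rise with ICS1. It also holds genes of SA metabolism that were lower, such as DMR6 and DLO1. Its median therefore does not test a joint rise of the synthesis genes alone. Adjusted over the list alone, 7 of its genes, ICS1 and PBS3 among them, were higher and 4 lower. The highest ICS2 level of 13.2 CPM would also be low if its reads had been assigned to ICS1, so that level alone does not decide. Reads shared by both genes would be divided by the estimation model, which leaves fractions. ICS2 had 213 estimated reads in sid2 DMSO replicate 1, and 91 and 42 in sid2 latrunculin B replicates 2 and 3. It had 95 in WT DMSO replicate 1, and 43, 35 and 33 in WT with latrunculin B. These whole numbers argue against reads divided between the paralogs in these libraries. In the other libraries ICS2 reads were divided between its own transcript models. The allele is not given, and no biological explanation was tested.

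Mitochondrial transcripts were higher under latrunculin B in WT. Their reads made up 0.00629% to 0.0330% of a library. Chloroplast genes had a median log2 fold change of -0.13, so no joint rise of both organelles was seen. Escape of organelle RNA from selection is not excluded, since a fall of chloroplast transcripts could hide it. Escape of mitochondrial RNA alone was not tested. Scaling does not explain the rise, since the lowest median of the mitochondrial genes over other scalings was 1.70. Whether transcripts per cell rose or polyadenylation changed could be biological, and the value of 1.70 does not separate these hypotheses.

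For comparisons of 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. The real grouping alone (1 of 10) reached its count in each: 8127 genes in WT against at most 0 in another split, 859 against 3 in the sid2-labelled leaves, 2001 against 11 under DMSO and 7870 against 0 under latrunculin B. Each other split mixes libraries of both groups, so a difference between the groups widens its spread and lowers its count. These low counts therefore do not measure chance. For the interaction 4 of 100 splits, the real grouping included, reached 4384, the highest other at 6757. Calls arose in 10 of the 100, the real grouping among them, and each of the 10 kept the latrunculin B libraries parted by genotype. The genotype difference under latrunculin B, with 7870 genes, therefore enters each of these splits. In the split with 6757 the genotype labels were exchanged under 1 treatment alone, which adds the genotype differences of both treatments. Such splits are not free of a genotype effect, so 4 of 100 does not measure chance for the interaction.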

How the results depend on the processing

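No called result for a named gene, no called list and no correlation changed direction under a setting run for it. Signs did change for values that passed under neither setting: the PR1 interaction, -0.52, was 0.64 without sid2 DMSO replicate 3, the ICS1 response in the sid2-labelled leaves, -0.14, was 0.01 with library size alone, and EDS5, PR2 and PR5 under DMSO changed sign without single libraries. Scaling by library size alone was added after the data were seen. With it and by limma on TPM the balance of higher and lower calls turned in 3 comparisons. It went from 4012 and 4115 in WT to 6818 and 2521 (6960 and 2380 by limma), from 2436 and 1948 in the interaction to 1820 and 2975 (1568 and 3497), and from 4020 and 3850 between genotypes under latrunculin B to 2731 and 6071 (2643 and 6096). Smaller turns came in WT with RLE size factors (4153 and 3992) and DESeq2 (4284 and 4138), and between genotypes under latrunculin B with RLE size factors (3881 and 4035), DESeq2 (4027 and 4153) and the 6 libraries of that comparison (4256 and 4285). The count in the sid2-labelled leaves, 859, was 1473 with library size alone, 1579 by DESeq2 and 358 in a fit of its 6 libraries. Leaving out single libraries gave 369 (without sid2 latrunculin B replicate 1) to 1472 (without sid2 DMSO replicate 3), with 496, 378, 447 and 419 between. Under DMSO 2001 became 1044 with 6 libraries and 1035 to 2347 without single libraries, with 1094 and 1291 among the lower values. Fits of 6 libraries, where fewer libraries estimate the spread, gave 8097 genes in WT and 8541 between genotypes under latrunculin B. The counts that fell most in such fits, 859 and 2001, involve sid2 with DMSO. That group had the largest median SD of log2 CPM, 0.282, against 0.197 to 0.221 in the others. The cause of the fall was not tested. With a log2 fold change of at least 1 as a further requirement, which removes genes by construction, counts were 4102 and 476 for latrunculin B in WT and in the sid2-labelled leaves, 2758 for the interaction, and 855 and 3873 between genotypes under DMSO and latrunculin B.

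Without single libraries WT gave 6814 to 8525 genes, the interaction 3394 to 4542, the genotypes under latrunculin B 6472 to 8340, and the ICS1 difference under DMSO 3.997 to 4.07. The correlation of the 2 responses, 0.406, ran from 0.316 to 0.436, was 0.373 without sid2 latrunculin B replicate 1, and 0.493 for genes with an average log2 CPM of at least 3. Of 140 list tests 71 passed, 69 to 78 without single libraries, and 6 with an estimated correlation. Where not stated, the cause was not tested. Gene calls were recomputed without single libraries for a chosen set of results, which was not drawn to cover every gene named above. Of 177 called results in this set, 5 lost the call in some leave-one-out fit. These were SARD1, CBP60G, SOT12, WRKY46 and AIG1 between genotypes under DMSO, which entered the set after values were seen. The share does not describe other genes named behind small counts. No paired analysis was possible because the labels pair no libraries.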

Other observations

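All 4 measured genes of N-hydroxypipecolic acid, an SA partner signal, rose in WT (4 adjusted over the list alone), and ALD1 and FMO1 rose in the sid2-labelled leaves (3 adjusted over the list alone). With fewer than 5 members this list had no set test. In WT 11 of 17 genes of indole glucosinolates and tryptophan rose and CYP79B3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.00352, and 0.296 with an estimated correlation; edgeR quasi-likelihood test for genes, Benjamini-Hochberg adjustment). In the sid2-labelled leaves 4 of these rose, 7 adjusted over the list alone (0.000165, and 0.157 with an estimated correlation). Of 13 autophagy genes 7 rose in WT and ATG8F fell, 7 and 2 adjusted over the list alone (0.006, and 0.381 with an estimated correlation), with the cargo receptor gene NBR1 (AT4G24690) up 3.31-fold. Of 10 sugar starvation genes 7 fell in WT and BCAT2 rose, 9 and 1 adjusted over the list alone. That list passed at 0.0174 (0.454 with an estimated correlation), but at 0.0846 without WT latrunculin B replicate 1 and 0.146 without WT DMSO replicate 3.

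Of 31 jasmonate genes 6 rose and 11 fell in WT, 6 and 11 adjusted over the list alone (0.715), with the jasmonate synthesis gene AOC2 (AT3G25770) down 2.04-fold. Of 17 ethylene genes 6 rose and 3 fell, 8 and 3 adjusted over the list alone (0.181; 0.0179 by fry and 0.0423 without WT DMSO replicate 3), and of 20 abscisic acid genes 7 rose and 3 fell, 7 and 4 adjusted over the list alone (0.404). Of 16 clock genes 9 rose and ELF3 and GRP7 fell, 9 and 3 adjusted over the list alone (0.163; 0.0179 by fry), and of 11 guard cell markers KAT1 and KAT2 rose and 6 fell, 2 and 8 adjusted over the list alone (0.36; 0.0316 by fry). HSP90.1 and HSP17.4 rose among 11 cytosolic heat shock genes, 2 adjusted over the list alone (0.466), and SOT17 and SUR1 rose and MYB29 and CYP83A1 fell among 16 aliphatic glucosinolate genes (0.913), where 1 lower gene and no higher gene passed adjusted over the list alone. CYCD3-1 and PCNA2 fell among 12 cell division genes, 1 adjusted over the list alone (0.363; 0.0316 by fry), and XCP1, ACL5 and FLA12 among 10 xylem markers, 2 adjusted over the list alone (0.234; 0.0179 by fry). SWEET12 rose and SULTR2-1 fell among 10 phloem markers, 1 and 1 adjusted over the list alone (0.542), and the SULTR2-1 call ended with library size alone (0.116) and by limma on TPM (0.415).

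In the sid2-labelled leaves under latrunculin B, SYP121 and VAMP722 rose among 10 secretion genes, 7 adjusted over the list alone (1.19e-05, and 0.157 with an estimated correlation). SAG13, SAG14 and SAUR36 rose among 15 senescence genes, 7 adjusted over the list alone (0.000135, and 0.103 with an estimated correlation), and RPS2 among 18 NLR genes, 3 adjusted over the list alone (0.000406, and 0.322 with an estimated correlation). HSP70 and HSP90.1 rose among 11 cytosolic heat shock genes, 2 adjusted over the list alone, and that list passed at 0.029. It did not pass with an estimated correlation (0.322), by fry (0.0577), with library size alone (0.0671), or without sid2 latrunculin B replicate 2 (0.0518) or sid2 DMSO replicate 2 (0.163).

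Between genotypes under DMSO 6 of 18 NLR genes were lower, 7 adjusted over the list alone (0.0141, 0.612 with an estimated correlation, and 0.0639 by fry; 0.128 without sid2 DMSO replicate 2 and 0.115 without WT DMSO replicate 3). The secretion genes EXO70B2, EXO70E2, SYP121 and SNAP33 were lower, 6 adjusted over the list alone (0.00563, 0.612 with an estimated correlation, and 0.0639 by fry). The photosynthesis list passed as higher with a median log2 difference of 0.23 (0.00568, 0.679 with an estimated correlation, and 0.231 by fry). Of 16 clock genes LHY, PRR9, RVE1 and LNK1 were higher and TOC1 and ELF3 lower, 9 and 2 adjusted over the list alone (0.0244, 0.612 with an estimated correlation, and 0.0873 by fry; 0.151 without sid2 DMSO replicate 1 and 0.0543 without WT DMSO replicate 1).

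Between genotypes under latrunculin B 13 of 27 pattern-triggered immunity genes were lower and 4 higher (0.00572, and 0.594 with an estimated correlation), and 8 of 10 secretion genes lower and EXO70B1 higher (0.000847, and 0.465), with the same counts adjusted over the list alone. Of 33 oxidative stress genes 18 were lower and CSD2 and ZAT10 higher, 21 and 2 adjusted over the list alone (0.00572, and 0.594). Of 16 aliphatic glucosinolate genes 10 were higher, 11 adjusted over the list alone (0.0132, and 0.65), and of 11 epidermis markers 7, or 9 adjusted over the list alone (0.00752, and 0.594). Of 10 sugar starvation genes 6 were higher, 6 also adjusted over the list alone (0.0182, and 0.594). The sugar starvation call ended without sid2 latrunculin B replicate 3 (0.156), sid2 DMSO replicate 1 (0.0578), WT latrunculin B replicate 1 (0.0882) or WT DMSO replicate 1 (0.0538). For these 6 lists the second bracketed value is the adjusted p with an estimated correlation.

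Of 40 mitochondrial genes 31 rose in WT with a median log2 fold change of 1.79, and none passed in the sid2-labelled leaves (0.07). Of 71 chloroplast genes 1 rose and 10 fell in WT. ARD3, AT3G47050 and WRKY38 had no reads in any of the 6 sid2-labelled libraries and at least 10 in every WT library, and no gene showed the mirrored pattern. Altered expression of the genes next to ICS1 was tested as a hypothesis. Of 20 neighbours 1 passed between genotypes in both treatments, and 69.4% of windows of neighbouring genes held as many, so the neighbourhood does not stand out.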
